A study of Mus musculus with 10 samples.

How the data were processed

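The material was RNA of a mouse embryonic stem cell line in 5 culture conditions, with 10 libraries, 2 per condition. Per the labels' protocols, RNA was extracted with a Qiagen kit and libraries were made with the NEBNext Ultra kit. Reads were aligned to mm10 with Bowtie2 and quantified with RSEM, per the submitters' processing notes, which also name DESeq2 and R 3.4.2; the versions of Bowtie2, RSEM and DESeq2 are not given in the sources used here. The deposited values are TPM, per the submitters' processing notes, in 1 table of 20494 lines and 10 columns. TPM keep no read number, so the depth per library and the precision it would give are unknown. The listed values of a library summed to 71.0% to 73.0% of the total that defines the unit, and the highest line held 5.43% to 7.63% of that sum. The gene lists, comparisons, tests and most alternatives were set before the data were examined.

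The pairing of symbols with values was checked with gene families whose members are broadly expressed or restricted to other tissues. In the first 9865 lines, 97.7% of 433 broadly expressed members and 8.2% of 122 restricted members had at least 5 TPM, with an area under the curve of 0.982. From line 10011 to line 17803 the value on a symbol's own line separated the families with an area of 0.541, against 0.982 for the value 1 line below. There 45.8% of broadly expressed members had at least 5 TPM on their own line and 93.5% on the next. In the last 2691 lines the value lying 2 lines below separated them, at 0.991. Gapdh, for one, stands beside 0.00389 TPM with 96.73 on the next line, and Sox2 beside 0.221 with 568.9 on the next. Genes are therefore named only in the first 9865 lines, of whose symbols 9757, or 98.9%, are in the RefSeq table for mm10. Counts of changed genes use every line, since they need no name. This limit was set after seeing the data. Among all lines, 108 neighbouring pairs held identical values, 34 of them in the named part, and were kept. Endogenous retroviruses were not analysed here, as 0 lines carry such names.

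Log2(TPM + 1) values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), with a mean per condition, all 10 libraries in the fit and no covariate. This left 5 residual degrees of freedom, and a median of 8.3 with the prior. A gene was tested at 1 TPM or more in at least 2 libraries, which kept 14578, of which 7962 could be named and 6616 could not. There were 8 pairwise comparisons, the contrast of the mean of the N2B27 conditions with SL and an F test over all conditions. Two-sided p-values were adjusted by Benjamini-Hochberg within each, with a threshold of 0.05. Of 46 gene lists, 42 had at least 3 tested members and were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists within a comparison. Members were also adjusted over the list alone. Camera with a correlation estimated per list, and fry, were run as alternatives. The replicate numbers 3 and 5 in the labels are not explained there and were not used as a block in the fit reported.

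Genes were named by a rule set in advance. It takes, per pairwise comparison, the 10 largest increases and the 10 largest decreases with an adjusted p below 0.05, a log2 change of at least 1 in size, at least 5 TPM in the higher group and the libraries of both groups apart. Predicted genes, Rik clones, small RNAs, ribosomal and histone genes and pseudogenes were skipped. For each list described it adds up to 4 passing members with the largest log2 change, or the 2 with the highest TPM where none passed. A fixed set of pluripotency, methylation, signalling, lineage, collagen and imprinted genes could always be named. Coordinates are those of mm10, GENCODE vM21.

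Alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalisation, only the 4 libraries compared, robust eBayes, a replicate block and each library left out in turn. Chosen after seeing the data were the named part alone, the fit without the libraries labelled 2iL and 2iL-F, the removal of 1126 lines that follow the fibroblast markers (r above 0.9) and list members by restored symbols. The fit was tested on simulated data for 2iL against SL, in 5 runs with 200 of 14578 genes changed. It recovered 73.6%, 97.6%, 99.2% and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 5.3% of calls false, and called 0 genes in the unchanged comparison. Of 200 random lists, 8 had a p below 0.05. Noise was drawn independently for each gene, so this does not give the error rate for lists whose genes vary together. Far more genes changed in the data than in the simulation. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.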

Results

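RNA-seq was done on an embryonic stem cell line of mouse strain label C57BL6X129S6F1 kept in 5 culture conditions, with 2 libraries per condition and 10 libraries in all. The series concerns genome stability in mouse embryonic stem cells, and its stated targets are pluripotency genes, endogenous retroviruses and epigenetic regulators. SL was a serum medium with 15% FBS and 1000 IU mLIF. The other 4 conditions used the serum-free N2B27 medium with 1000 IU mLIF and 3 µM Chir99021, an inhibitor of the kinase GSK3. To this, 2iL added 1 µM PD0325901, a MEK inhibitor, A2iL added 1.5 µM CGP77675, a Src inhibitor, and LCDM added 2 µM each of compounds written Dim and Mih. The condition 2iL-F had the 2iL medium. Per the labels, 2iL-F was grown without feeder cells and the other 4 conditions with them. The values are TPM, a unit scaled to the library total, which keeps no read depth, so the depth behind each value is unknown. The listed values of a library summed to between 71.0% and 73.0% of the total that defines the unit. Below, TPM values are means ± SD with n = 2 libraries per condition, and changes are differences of log2(TPM + 1) ± SE from limma, which understate the change of genes with low TPM. Genes are called at a Benjamini-Hochberg adjusted p below 0.05. Members of a list not counted as risen or fallen did not pass. Counts of list members adjusted over the list alone equalled those over all genes tested unless both are given.

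The 2 libraries of a condition had Pearson correlations across genes of 0.9925 to 0.9939, and 97.4% to 97.8% of the 14578 tested genes lay within 1.5-fold between them. Between conditions the mean correlation was lowest for SL and 2iL, at 0.825, and highest for A2iL and 2iL-F, at 0.954. The first principal component held 59.3% of the variance and ran from SL, at -67.07 and -67.61, to the libraries labelled 2iL, at 84.01 and 83.58. A test for any difference among the 5 conditions passed for 13139 genes, or 90.1%. Nothing states that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. In the lower part of the deposited table the gene symbols do not stand beside their own values, as described with the processing. Genes are therefore named only from the upper part, where 7962 genes were tested, while counts of changed genes cover all 14578.

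**Figure D1:**
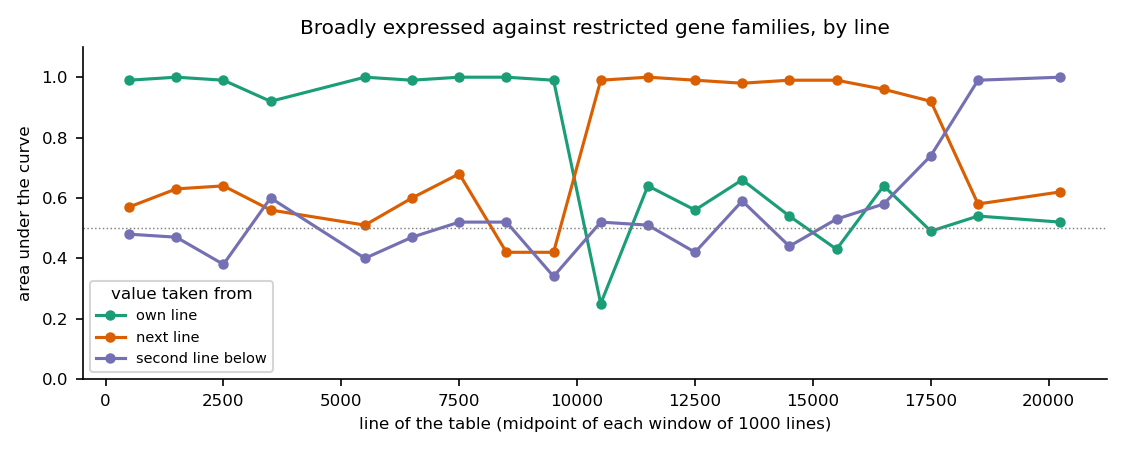
Area under the curve with which the value on a symbol's own line, the next line or the second line below separates broadly expressed from restricted gene families, in windows of 1000 lines. A value of 1 is full separation; the curve of the own line gives way to that of the next line between lines 9865 and 10011.

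Transcripts of fibroblasts, the usual feeder cells, did not follow the feeder labels. Col1a1, which encodes a chain of type I collagen (chromosome 11, 94936224 to 94953042 of mm10), had 379 ± 19.3 TPM in SL, 394 ± 18.7 in A2iL and 107 ± 2.32 in LCDM. The libraries labelled 2iL, described as grown with feeders, had 0.232 ± 0.0447 TPM, and those labelled 2iL-F, described as grown without, had 1016 ± 59.3. Col3a1, the chain of type III collagen (chromosome 1, 45311538 to 45349706), had 29.0 ± 0.280 TPM in SL and 358 ± 3.15 in 2iL-F, and was listed at 0.027 and 0 in the 2 libraries labelled 2iL. Lox, which crosslinks collagen, was listed at 0 in both libraries labelled 2iL and had 239.5 ± 0.462 TPM in 2iL-F. The summed TPM of the 43 fibroblast markers was 7941 ± 223 in SL, 1029 ± 15.6 in 2iL, 4880 ± 31.8 in A2iL, 1698 ± 31.8 in LCDM and 5298 ± 134 in 2iL-F. At least 1 TPM of 17 of these markers was found in both libraries labelled 2iL, so the list is not specific to fibroblasts, and 1 marker is also in another list. Because of this conflict, "2iL" and "2iL-F" below mean the libraries that carry those labels, and any direction drawn from them with respect to feeders depends on the labels. An exchange of these labels would leave the medium as stated, since both name the same medium.

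**Figure D2:**
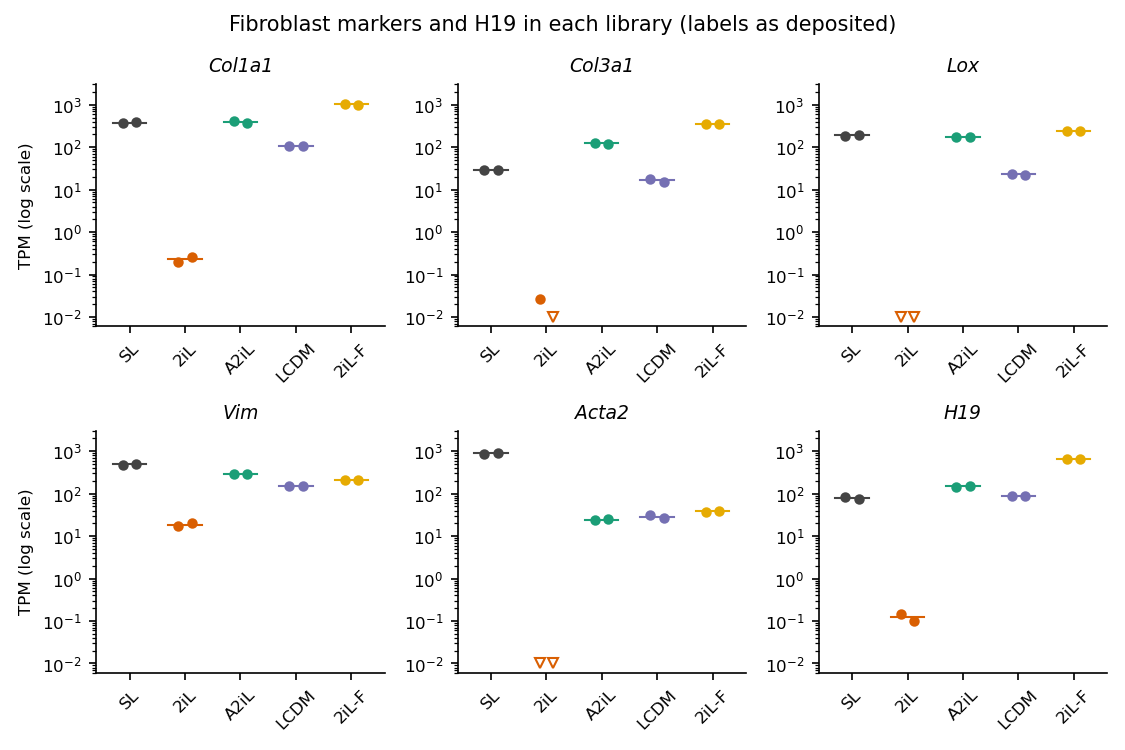
TPM on a log scale of 5 fibroblast markers and of H19 in each library, by condition label; filled points are libraries, short lines are means of 2 libraries, and open triangles are libraries listed below 0.01 TPM. Col1a1 lies at 0.232 TPM in the libraries labelled 2iL, against 107 to 1016 in the other 4 conditions.

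The first comparison, 2iL against SL, asks how inhibition of MEK and GSK3 in serum-free medium differs from serum with LIF. Naive pluripotency genes were higher in 2iL and primed or formative genes lower. Tfcp2l1, a transcription factor of the naive network (chromosome 1, 118627945 to 118685168), had 220.2 ± 26.6 TPM against 18.4 ± 0.0497 in SL, a change of 3.50 ± 0.07. Nanog, a core pluripotency factor (chromosome 6, 122707489 to 122714633), had 668 ± 86.4 against 134 ± 1.99 TPM (2.31 ± 0.08). The de novo DNA methyltransferase genes Dnmt3b (-4.55 ± 0.07) and Dnmt3a (-3.39 ± 0.06) and their cofactor Dnmt3l (-4.57 ± 0.07) all fell, while Uhrf1, which recruits the maintenance enzyme, rose by 1.35 ± 0.04. Among naive genes, 11 of 16 tested members rose and 5 fell (adjusted p = 0.0165, and adjusted p = 0.588 with an estimated correlation). Pecam1, an adhesion molecule of naive cells, rose by 3.31, and Gbx2, a homeobox gene, fell by 3.00 on the log2 scale. For primed and formative genes, 9 of 12 tested members fell and 3 rose (adjusted p = 0.0138, and adjusted p = 0.588 with an estimated correlation), and passing members included Lef1, a Wnt effector, at -4.31 (-7.07 with a pseudocount of 0.1), and Cdh2, which encodes N-cadherin, at -3.98. In 2iL-F, with the same medium, Cdh2 was higher than in 2iL by 2.44 and Lef1 by 0.7 on the log2 scale.

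Targets of FGF-ERK signalling, which PD0325901 blocks at MEK, were lower in 2iL: 20 of 22 tested members fell and 2 rose, with a median of -2.43 (adjusted p = 1.14e-06, and adjusted p = 0.125 with an estimated correlation). Fosb and Fos, immediate early genes, changed by -6.23 ± 0.06 and -5.20 ± 0.04, and Spry4, a feedback inhibitor of the pathway, by -4.48 ± 0.07. In 2iL-F, with the same PD0325901, Spry4 was also low (-4.34 against SL), but Fos was near its SL level, as given below. The fall of Fos thus did not follow the inhibitor alone. Fibroblast transcripts were also lower in the libraries labelled 2iL, against their feeder label: 39 of 43 tested members fell and 3 rose (adjusted p = 1.08e-14, and adjusted p = 0.125 with an estimated correlation). The interferon response list moved the same way, with Isg15, an interferon-induced ubiquitin-like protein, at 0.113 TPM against 91.5 in SL; 16 of 17 tested members fell and 1 rose (adjusted p = 1.88e-05, and adjusted p = 0.125 with an estimated correlation). H19, an imprinted noncoding RNA expressed in fibroblasts, fell from 79.2 ± 4.62 to 0.121 ± 0.0298 TPM. Replication stress checkpoint genes had 19 of 28 tested members that rose and 3 that fell (adjusted p = 0.0165, and adjusted p = 0.632 with an estimated correlation), and double-strand break repair genes 21 of 36 tested members that rose and 4 that fell (adjusted p = 0.0297, and adjusted p = 0.632 with an estimated correlation). In the opposite direction to the fibroblast markers, genes of amino acid and ATF4 responses rose, with 27 of 32 tested members that rose and 2 that fell (adjusted p = 1.14e-06, and adjusted p = 0.272 with an estimated correlation). Nupr1, a stress-induced regulator, had 127 ± 2.03 against 7.33 ± 0.578 TPM, and Gpt2, a mitochondrial alanine aminotransferase, 184 ± 4.41 against 17.4 ± 1.96. On the log2(TPM + 1) scale the largest increase among named genes was that of Aqp3, a water and glycerol channel, from 3.71 ± 0.0353 to 251 ± 4.79 TPM (5.74 ± 0.05). By the ratio of mean TPM, Aldh1l1 (100) and Ly6g6e (73.18) rose more than Aqp3 (67.61). In all, 11321 of 14578 genes changed, 5353 higher and 5968 lower in 2iL, of which 1875 and 2402 by at least 1 on the log2 scale. The share of higher calls was 47.3%, but 52.5% with quantile normalisation and 52.4% without genes that follow the fibroblast markers. These directions come from libraries labelled 2iL, whose feeder state is in doubt.

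A2iL against SL asks the same of a medium with GSK3 and Src inhibitors and no MEK inhibitor. Naive genes were higher here too, and Dnmt3a, Dnmt3b and Dnmt3l were lower. Esrrb, a naive pluripotency factor (chromosome 12, 86361117 to 86521628), had 231 ± 6.02 TPM against 69.6 ± 4.33 in SL (1.72 ± 0.05), and Tbx3, another factor of this network, rose by 2.75 ± 0.06. Among naive genes, 12 of 16 tested members rose and 2 fell (adjusted p = 1.18e-06, and adjusted p = 0.471 with an estimated correlation). Dnmt3a changed by -1.85 ± 0.06, Dnmt3l by -1.38 ± 0.07 and Dnmt3b by -1.15 ± 0.07, and the difference between A2iL and 2iL is tested further below. For primed and formative genes, 9 of 12 tested members fell and 1 rose (adjusted p = 0.000666, and adjusted p = 0.471 with an estimated correlation), with Krt18, a keratin, at -4.13. The FGF-ERK targets had no common direction, as 8 of 22 tested members rose and 8 fell (adjusted p = 0.809): Fos rose from 160.5 ± 1.95 to 476 ± 4.60 TPM, and Myc, a growth regulator, fell from 68.6 ± 2.08 to 19.6 ± 0.0261.

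Among other groups in A2iL, the ATF4 and amino acid response had 28 of 32 tested members that rose and 1 that fell (adjusted p = 6.43e-12, and adjusted p = 0.32 with an estimated correlation), with Chac1, which degrades glutathione, at 2.83 ± 0.06 and Asns, asparagine synthetase, at 1.72 ± 0.05. Cholesterol synthesis genes rose in like manner, where 16 of 19 tested members rose and 2 fell (adjusted p = 5e-05, and adjusted p = 0.471 with an estimated correlation), Nsdhl by 0.90. Among the largest increases were those of Steap4, a metalloreductase, from 0.627 ± 0.104 to 37.5 ± 0.542 TPM, complement C3 from 0.380 ± 0.114 to 28.0 ± 0.481, Lcn2, an iron-binding lipocalin, from 0.163 ± 0.0287 to 11.8 ± 0.0384, and Dcn, a fibroblast proteoglycan, from 6.56 ± 0.332 to 108 ± 3.23. Among the largest decreases were those of the contractile genes Acta2 and Tagln, at -5.14 and -5.11. As a whole the fibroblast markers did not pass, as 23 of 43 tested members fell and 10 rose (adjusted p = 0.0813), and neither did the interferon genes (adjusted p = 0.0724). With median-of-ratios scaling both did, at adjusted p = 0.0448 and adjusted p = 0.0362, and with members by restored symbols the fibroblast list did, at adjusted p = 0.0289. In all, 7844 genes changed, 3196 higher and 4648 lower, with 544 and 693 by at least 1 on the log2 scale. The share of higher calls among them was 40.7%, and 51.4% after median-of-ratios scaling.

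LCDM against SL asks the same of the medium with Dim and Mih in place of a second kinase inhibitor. Pluripotency genes, germline genes and genes of DNA replication and division were higher in LCDM, and p53 targets were lower. Nanog rose from 134 ± 1.99 to 462 ± 16.4 TPM (1.78 ± 0.08), and Tbx3 from 8.42 ± 0.535 to 83.9 ± 2.95. Core pluripotency genes had 6 of 9 tested members that rose and 0 that fell (adjusted p = 0.0206, and adjusted p = 0.468 with an estimated correlation), and naive genes 13 of 16 tested members that rose and 2 that fell (adjusted p = 2.21e-05, and adjusted p = 0.354 with an estimated correlation). Of germline genes that depend on DNA methylation for silencing, 12 of 17 tested members rose and 1 fell (adjusted p = 0.00124, and adjusted p = 0.389 with an estimated correlation). They included Stra8, which licenses entry into meiosis, with 42.4 ± 2.17 against 13.8 ± 0.947 TPM, and Dazl, a germ cell RNA-binding protein, with 9.76 ± 0.356 against 1.14 ± 0.183. Sohlh2, a germ cell transcription factor, rose by 2.88 ± 0.11. Among p53 targets, 17 of 25 tested members fell and 4 rose, with 5 that rose and 17 that fell adjusted over the list alone (adjusted p = 0.023, and adjusted p = 0.536 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 173 ± 8.58 against 486 ± 2.99 TPM and Perp, a membrane protein of the p53 pathway, at -2.21.

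Of the lists on genome stability, replication stress, double-strand break repair and spindle genes were higher in LCDM than in SL. Excision and mismatch repair (19 of 37 tested members rose and 5 fell, adjusted p = 0.0592, and adjusted p = 0.00657 with members by restored symbols) and telomere maintenance (7 of 16 tested members rose and 4 fell, adjusted p = 0.478) did not pass. For the replication stress checkpoint, 24 of 28 tested members rose and 0 fell (adjusted p = 5.12e-05, and adjusted p = 0.468 with an estimated correlation), with Cdc45, a part of the replicative helicase, at 0.97 ± 0.06. Double-strand break repair had 26 of 36 tested members that rose and 4 that fell, with 27 that rose and 4 that fell adjusted over the list alone (adjusted p = 0.000871, and adjusted p = 0.536 with an estimated correlation), among them Fanca of the Fanconi anaemia pathway at 1.14 and Parp1, a sensor of DNA breaks, at 1.03. In the spindle and segregation list, 17 of 31 tested members rose and 3 fell (adjusted p = 0.0114, and adjusted p = 0.541 with an estimated correlation), with securin, Pttg1, at 1.43 ± 0.05. Lists of S phase and G2-M genes moved the same way (adjusted p = 0.00271 and adjusted p = 0.00086; with an estimated correlation, adjusted p = 0.468 and adjusted p = 0.536). Fibroblast markers were lower, as 39 of 43 tested members fell and 2 rose (adjusted p = 3.64e-15, and adjusted p = 0.176 with an estimated correlation), and so were interferon genes, as 16 of 17 tested members fell and 1 rose (adjusted p = 5.51e-07, and adjusted p = 0.0804 with an estimated correlation). What part less fibroblast RNA in LCDM has in the p53, division and repair differences from SL was not tested. FGF-ERK targets had 17 of 22 tested members that fell and 3 that rose (adjusted p = 0.000292, and adjusted p = 0.332 with an estimated correlation), with Lif at -2.33. In all, 9607 genes changed, 4700 higher and 4907 lower, with 879 and 1482 by at least 1 on the log2 scale. The share of higher calls was 48.9%, but 54.6% with quantile normalisation and 54.3% without genes that follow the fibroblast markers.

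2iL-F against SL repeats the 2iL medium in the libraries labelled as free of feeders, although their fibroblast marker sum was 5298 ± 134 TPM against 7941 ± 223 in SL. Naive genes were again higher, and FGF-ERK targets and primed genes lower. Tfcp2l1 had 203 ± 0.375 TPM against 18.4 ± 0.0497 (3.39 ± 0.07), and Nanog 648 ± 6.13 against 134 ± 1.99 (2.27 ± 0.08). Among naive genes, 13 of 16 tested members rose and 2 fell (adjusted p = 9.28e-06, and adjusted p = 0.49 with an estimated correlation), and among core genes, 7 of 9 tested members rose and 1 fell (adjusted p = 0.012, and adjusted p = 0.5 with an estimated correlation, and adjusted p = 0.379 with members by restored symbols, a setting chosen after seeing the data). Spry4 changed by -4.34 ± 0.08 and Dnmt3l by -4.31 ± 0.07. For FGF-ERK targets, 16 of 22 tested members fell and 2 rose (adjusted p = 0.000129, and adjusted p = 0.452 with an estimated correlation), and for primed and formative genes, 9 of 12 tested members fell and 2 rose (adjusted p = 0.00566, and adjusted p = 0.5 with an estimated correlation).

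Wnt-beta-catenin targets were lower in 2iL-F although Chir99021 stabilises beta-catenin: 13 of 18 tested members fell and 3 rose (adjusted p = 0.0129, and adjusted p = 0.49 with an estimated correlation), with Wnt8a, a ligand, at -4.69 (-7.70 with a pseudocount of 0.1) and Lef1 at -3.61. Cholesterol and fatty acid synthesis genes rose, the first with 15 of 19 tested members that rose and 2 that fell, with 15 that rose and 3 that fell adjusted over the list alone (adjusted p = 0.000129, and adjusted p = 0.49 with an estimated correlation) and the second with 12 of 16 tested members that rose and 3 that fell (adjusted p = 0.00536, and adjusted p = 0.5 with an estimated correlation). Fads2, a fatty acid desaturase, had 214 ± 3.30 against 70.9 ± 4.49 TPM. Replication stress checkpoint genes had 17 of 28 tested members that rose and 3 that fell (adjusted p = 0.022, and adjusted p = 0.75 with an estimated correlation). Serpina3n, an acute-phase protease inhibitor, showed the largest increase among named genes, from 0.230 ± 0.0695 to 48.9 ± 0.590 TPM (5.34 ± 0.11). The fibroblast markers moved both ways, as 25 of 43 tested members fell and 16 rose (adjusted p = 0.389): Col3a1 rose by 3.58 and Acta2 changed by -4.51. In all, 9540 genes changed, 4099 higher and 5441 lower, with 1129 and 1223 by at least 1 on the log2 scale. Higher calls made up 43.0%, and 49.8% with median-of-ratios scaling and 47.8% with quantile normalisation.

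2iL-F against 2iL compares one medium under both feeder labels. Fibroblast and interferon transcripts were higher under the label without feeders, and germline genes were lower. Of these markers, 40 of 43 tested members rose and 2 fell, with a median of 4.54 (adjusted p = 4.17e-25, and adjusted p = 0.0606 with an estimated correlation), among them Col1a1 (9.69 ± 0.06) and Col1a2, its partner chain (7.95 ± 0.05). Interferon genes moved with them: 17 of 17 tested members rose and 0 fell (adjusted p = 9.97e-10, and adjusted p = 0.0375 with an estimated correlation), where Isg15 had 32.4 ± 2.18 TPM in 2iL-F and 0.113 ± 0.00495 in 2iL. H19 (chromosome 7, 142575529 to 142578143) rose from 0.121 ± 0.0298 to 669 ± 4.29 TPM and Loxl2, a lysyl oxidase counted with the hypoxia genes, from 0.0152 ± 0.0216 to 76.7 ± 1.99; of hypoxia genes, 12 of 17 tested members rose and 4 fell (adjusted p = 0.0219, and adjusted p = 0.664 with an estimated correlation). FGF-ERK targets were higher, as 13 of 22 tested members rose and 3 fell (adjusted p = 0.000741, and adjusted p = 0.328 with an estimated correlation): Fos had 160.2 ± 2.23 against 3.39 ± 0.106 TPM, while Spry4 had 0.386 ± 0.0608 against 0.258 ± 0.0410 and did not pass (adjusted p = 0.143). With a pseudocount of 0.1 the Spry4 difference was 0.44 (adjusted p = 0.0132), and with quantile normalisation it was -0.39 (adjusted p = 0.000846).

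Core pluripotency genes as a list did not pass. They had a median of 0.11, as 3 of 9 tested members rose and 2 fell (adjusted p = 0.545). Nanog had 648 ± 6.13 TPM in 2iL-F and 668 ± 86.4 in 2iL (adjusted p = 0.691, and 0.011 without 2iL replicate 3). Germline genes were lower in 2iL-F, as 12 of 17 tested members fell and 0 rose (adjusted p = 0.00714, and adjusted p = 0.664 with an estimated correlation, and adjusted p = 0.134 with members by restored symbols), with Rhox6, a homeobox gene of the X chromosome, at 6.82 ± 0.112 against 44.8 ± 0.128 TPM. The epithelial claudins Cldn7 and Cldn6 fell by 3.65 and 3.32 on the log2 scale, and Gata2, a haematopoietic and trophoblast factor, by 3.24. ATF4 and amino acid response genes were lower, as 24 of 32 tested members fell and 5 rose (adjusted p = 0.0028, and adjusted p = 0.664 with an estimated correlation), with Gpt2 at -1.61. In all, 8995 genes changed, 4262 higher and 4733 lower, with 1231 and 682 by at least 1 on the log2 scale. Of these calls, 47.4% were higher, and 49.7% with median-of-ratios scaling, but 43% with quantile normalisation and 40.2% without genes that follow the fibroblast markers. If the labels were exchanged, each of these directions would be the opposite with respect to feeders.

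**Figure D3:**
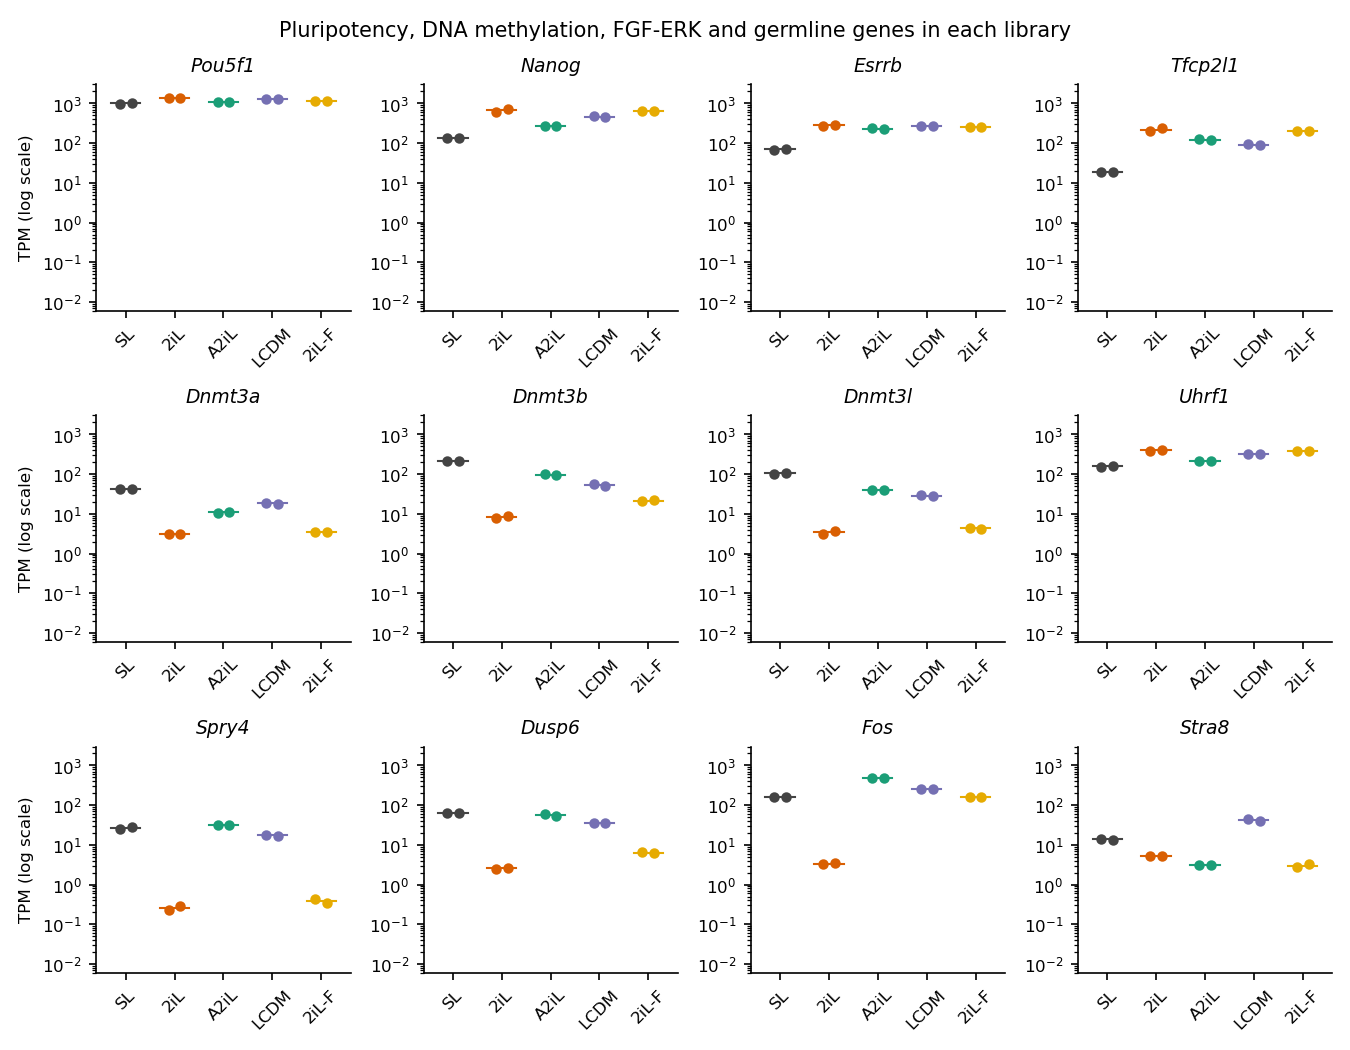
TPM on a log scale of 12 genes of pluripotency, DNA methylation, FGF-ERK signalling and the germline in each library, by condition label; points are libraries and short lines are means of 2 libraries. Spry4 lies at 0.258 and 0.386 TPM under the labels 2iL and 2iL-F, against 17.4 to 31.9 in the conditions without PD0325901.

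A2iL against 2iL exchanges the MEK inhibitor for a Src inhibitor. FGF-ERK targets and the de novo methyltransferase genes were higher in A2iL. Of the FGF-ERK targets, 20 of 22 tested members rose and 2 fell, with a median of 1.99 (adjusted p = 4.46e-09, and adjusted p = 0.0791 with an estimated correlation). Spry4 had 31.9 ± 0.727 TPM against 0.258 ± 0.0410, and Dusp6, an ERK phosphatase (chromosome 10, 99263231 to 99267489), 56.9 ± 3.52 against 2.56 ± 0.0982. Dnmt3b rose from 8.28 ± 0.777 to 96.9 ± 3.20 TPM, Dnmt3l from 3.43 ± 0.331 to 39.5 ± 0.179, and Dnmt3a rose by 1.54 ± 0.06. Wnt-beta-catenin targets were higher, as 12 of 18 tested members rose and 2 fell (adjusted p = 0.0343, and adjusted p = 0.67 with an estimated correlation), with Axin2, a feedback regulator of the pathway (chromosome 11, 108920349 to 108950783), at 1.37 ± 0.06. Fibroblast transcripts differed by a marker sum of 4880 ± 31.8 TPM in A2iL against 1029 ± 15.6 in 2iL: 39 of 43 tested members rose and 4 fell (adjusted p = 2.18e-18, and adjusted p = 0.0791 with an estimated correlation). Interferon genes rose beside them, as 17 of 17 tested members rose and 0 fell (adjusted p = 1.07e-07, and adjusted p = 0.068 with an estimated correlation).

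Lower in A2iL than in 2iL were genes of DNA demethylation, where 7 of 10 tested members fell and 0 rose (adjusted p = 0.0343, and adjusted p = 0.67 with an estimated correlation). Of the 16 symbols on this list 10 could be named, and Tet1 and Tet2 were not among them. Gadd45b, a stress-inducible gene tied to demethylation, had 17.1 ± 1.48 against 144 ± 5.98 TPM, and Idh2, a mitochondrial isocitrate dehydrogenase, 82.2 ± 3.01 against 271 ± 26.0. Germline genes had 10 of 17 tested members that fell and 0 that rose (adjusted p = 0.0343, and adjusted p = 0.67 with an estimated correlation, and adjusted p = 0.0545 with a pseudocount of 0.1), with Rhox6 at -2.88. The replication stress checkpoint had 17 of 28 tested members that fell and 3 that rose (adjusted p = 0.0343, and adjusted p = 0.684 with an estimated correlation), with Cdt1, a replication licensing factor, at -0.95 ± 0.07. Nanog fell from 668 ± 86.4 to 267 ± 3.90 TPM (-1.31 ± 0.08), whereas core genes as a list did not pass (adjusted p = 0.192). In all, 10127 genes changed, 4843 higher and 5284 lower, with 1658 and 1337 by at least 1 on the log2 scale. Of these calls, 47.8% were higher, and 50% with median-of-ratios scaling, but 45.6% with quantile normalisation and 41.5% without genes that follow the fibroblast markers. These directions rest on libraries labelled 2iL whose fibroblast transcripts conflict with their label.

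LCDM against 2iL exchanges the MEK inhibitor for Dim and Mih. Again FGF-ERK targets, Dnmt3a, Dnmt3b, Dnmt3l and fibroblast transcripts were higher, and genes of the ATF4 response and trophoblast were lower. For FGF-ERK targets, 18 of 22 tested members rose and 2 fell (adjusted p = 1.34e-06, and adjusted p = 0.174 with an estimated correlation), with Fos at 253 ± 3.38 against 3.39 ± 0.106 TPM. Fos was also higher in 2iL-F than in 2iL, which share PD0325901, as given above. Id3, a target of BMP signalling, had 63.7 ± 3.77 TPM in LCDM and was listed at 0.049 and 0 in the 2 libraries labelled 2iL. Like Fos, Id3 was also higher in 2iL-F than in 2iL, by 5.34 on the log2 scale. Dnmt3l rose by 2.73 ± 0.07 and Dnmt3a by 2.23 ± 0.06. Fibroblast markers had 38 of 43 tested members that rose and 5 that fell (adjusted p = 2.98e-15, and adjusted p = 0.174 with an estimated correlation). For ATF4 and amino acid response genes, 22 of 32 tested members fell and 2 rose (adjusted p = 1.21e-05, and adjusted p = 0.367 with an estimated correlation), with Ddit3, a stress-induced transcription factor, at 19.8 ± 0.476 against 96.8 ± 11.8 TPM. Trophoblast genes had 14 of 19 tested members that fell and 3 that rose (adjusted p = 0.00306, and adjusted p = 0.367 with an estimated correlation), with Gata2 at 1.19 ± 0.0810 against 28.2 ± 1.57 TPM. DNA demethylation genes had 7 of 10 tested members that fell and 0 that rose (adjusted p = 0.00633, and adjusted p = 0.484 with an estimated correlation), with Gadd45b at -2.33. Tet1 and Tet2 were not among the members tested. In all, 9075 genes changed, 5000 higher and 4075 lower, with 969 and 853 by at least 1 on the log2 scale. Higher calls made up 55.1%, and 49.7% without genes that follow the fibroblast markers. As above, these directions rest on libraries labelled 2iL, whose feeder state is in doubt.

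LCDM against A2iL compares the 2 N2B27 media without a MEK inhibitor, and neither group carries the doubted labels. Germline genes and genes of division and repair were higher in LCDM, and p53 targets, interferon genes and fibroblast transcripts were lower. Stra8 had 42.4 ± 2.17 TPM in LCDM against 3.09 ± 0.00193 in A2iL (3.41 ± 0.08), Smc1b, a cohesin of meiotic chromosomes, 6.60 ± 0.293 against 0.217 ± 0.108, and Mov10l1, a helicase of the piRNA pathway, 6.87 ± 0.0468 against 0.790 ± 0.272. Of the germline genes, 14 of 17 tested members rose and 1 fell, with 15 that rose and 1 that fell adjusted over the list alone (adjusted p = 7.31e-05, and adjusted p = 0.486 with an estimated correlation). The spindle and segregation list had 22 of 31 tested members that rose and 1 that fell, with 26 that rose and 1 that fell adjusted over the list alone (adjusted p = 0.000219, and adjusted p = 0.605 with an estimated correlation), with Pttg1 at 1.23 ± 0.05 and Aurkb, the chromosomal passenger kinase, at 0.83 ± 0.04. For the replication stress checkpoint, 22 of 28 tested members rose and 0 fell, with 23 that rose and 0 that fell adjusted over the list alone (adjusted p = 5.73e-05, and adjusted p = 0.605 with an estimated correlation), and for double-strand break repair, 20 of 36 tested members rose and 0 fell, with 21 that rose and 1 that fell adjusted over the list alone (adjusted p = 0.00713, and adjusted p = 0.711 with an estimated correlation), with Rad51c, a recombination factor, at 0.89 ± 0.07.

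Among p53 targets in this pair, 17 of 25 tested members fell and 3 rose (adjusted p = 0.000483, and adjusted p = 0.605 with an estimated correlation), where Cdkn1a had 173 ± 8.58 against 523 ± 7.47 TPM and the death receptor Fas 2.02 ± 0.261 against 12.9 ± 0.206. Summed TPM of p53 targets was 2194 in SL, 2208 in A2iL and 2056 in 2iL-F, against 1393 in LCDM and 1810 in 2iL. The conditions with the higher p53 sums also had the higher fibroblast sums given above. What part fibroblast RNA has in the p53, division and repair differences was not tested. Interferon genes had 17 of 17 tested members that fell and 0 that rose (adjusted p = 1.8e-11, and adjusted p = 0.0255 with an estimated correlation), and fibroblast markers 37 of 43 tested members that fell and 3 that rose (adjusted p = 1.08e-18, and adjusted p = 0.0928 with an estimated correlation). The chemokines Ccl2 and Cxcl1 had 21.4 ± 0.609 and 11.6 ± 0.232 TPM in LCDM, and 598 ± 24.1 and 238 ± 12.1 in A2iL. FGF-ERK targets were lower, as 16 of 22 tested members fell and 1 rose (adjusted p = 3.04e-07, and adjusted p = 0.0928 with an estimated correlation), with Ier3, an early response gene, at -2.86, and Dusp9, another ERK phosphatase, rose by 2.51 ± 0.07. In all, 7873 genes changed, 4534 higher and 3339 lower, with 382 and 935 by at least 1 on the log2 scale. The share of higher calls was 57.6%, but 47.6% after median-of-ratios scaling and 64% without genes that follow the fibroblast markers.

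**Figure D4:**
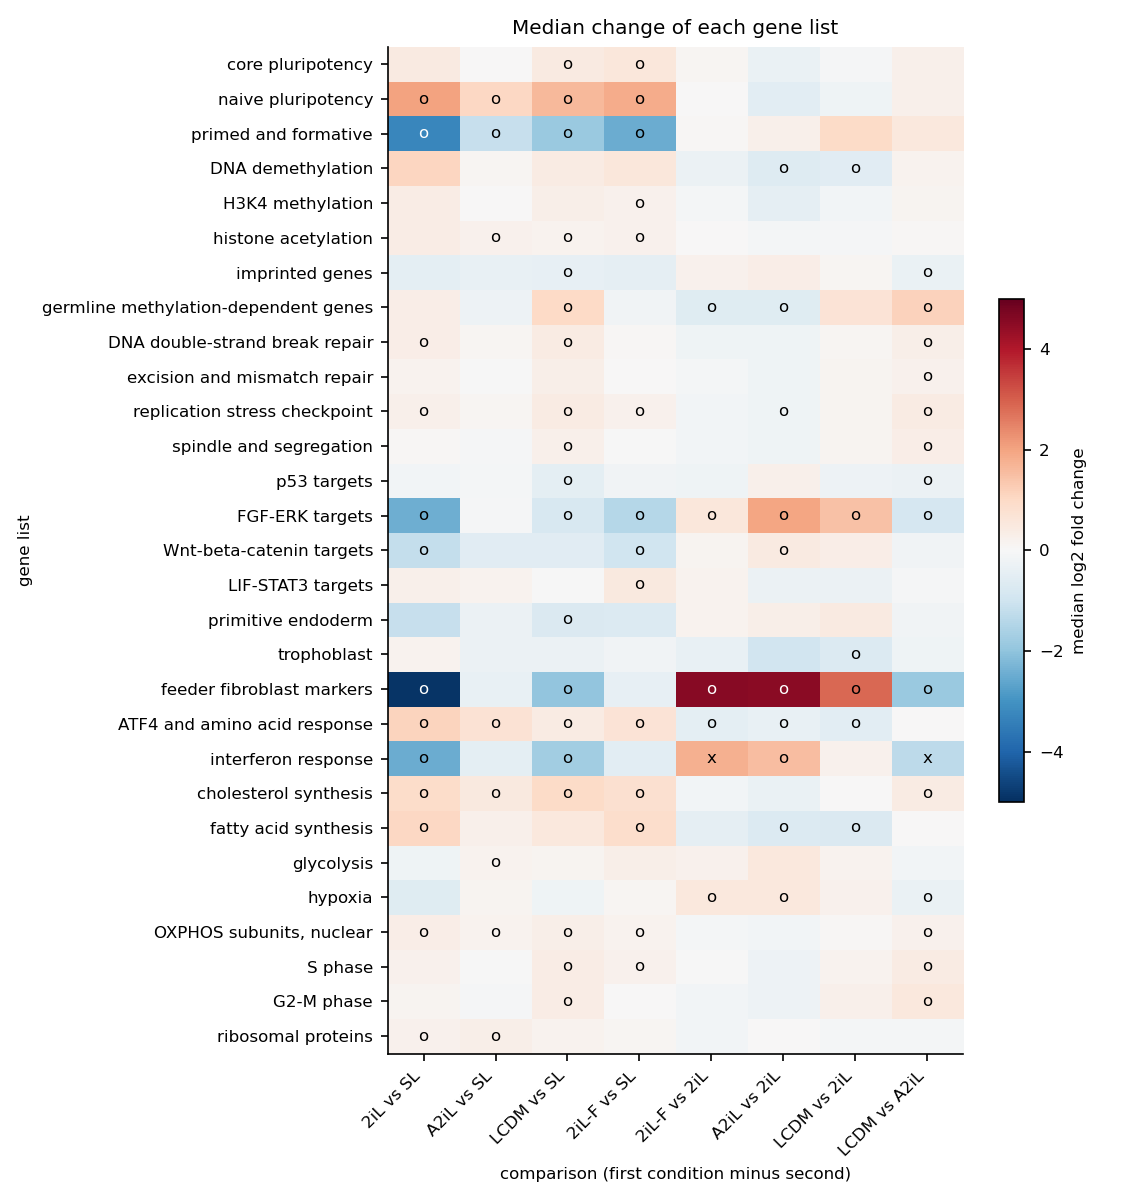
Median log2 fold change of the 29 gene lists that passed in at least 1 comparison (colour; lists from top to bottom, comparisons from left to right). Circles mark an adjusted p below 0.05 with the preset correlation of 0.01, and crosses mark the 2 calls, both of the interferon list, that also held with an estimated correlation.

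The mean of the 4 N2B27 conditions against SL gives the average difference of the serum-free media with Chir99021. Some of the conditions can drive it, so a passing result need not be shared by all. Naive genes were higher on average and primed genes lower. Among naive genes, 14 of 16 tested members rose and 2 fell (adjusted p = 1.68e-05, and adjusted p = 0.373 with an estimated correlation), Tfcp2l1 by 2.95 ± 0.06 and Tbx3 by 3.00 ± 0.04. Among primed and formative genes, 9 of 12 tested members fell and 3 rose (adjusted p = 0.0071, and adjusted p = 0.436 with an estimated correlation), with Fgf8, a growth factor, at -3.62. ATF4 and amino acid response genes had 27 of 32 tested members that rose and 2 that fell (adjusted p = 4.38e-08, and adjusted p = 0.182 with an estimated correlation), and nuclear genes of oxidative phosphorylation 31 of 45 tested members that rose and 1 that fell, with 32 that rose and 2 that fell adjusted over the list alone (adjusted p = 0.000154, and adjusted p = 0.436 with an estimated correlation), among them Cox5a at 0.81. Replication stress checkpoint genes had 19 of 28 tested members that rose and 0 that fell (adjusted p = 0.00432, and adjusted p = 0.539 with an estimated correlation), and double-strand break repair genes 20 of 36 tested members that rose and 5 that fell (adjusted p = 0.0153, and adjusted p = 0.654 with an estimated correlation). The mean log2(TPM + 1) of the first list was 5.34 in SL, 5.7 in 2iL, 5.36 in A2iL, 5.77 in LCDM and 5.55 in 2iL-F. For the second it was 3.8, 4.12, 3.92, 4.18 and 3.91 in the same order. A2iL thus hardly shared the rise of the first list, and the rise of the second was larger in 2iL and LCDM. Fibroblast markers moved against the lists that rose: 38 of 43 tested members fell and 3 rose (adjusted p = 3.13e-11, and adjusted p = 0.182 with an estimated correlation). The sum of these markers was higher in SL than in each other condition, as given above. As a list they did not pass in A2iL or 2iL-F against SL. In 2iL-F they moved both ways, and Col1a1 and Col3a1 were higher than in SL. Histone acetylation genes had 13 of 23 tested members that rose and 3 that fell (adjusted p = 0.0153, and adjusted p = 0.539 with an estimated correlation), with the acetyltransferase Kat6b at 1.08, and ribosomal protein genes 15 of 23 tested members that rose and 1 that fell (adjusted p = 0.0153, and adjusted p = 0.539 with an estimated correlation). In all, 10421 genes changed, 4737 higher and 5684 lower. Higher calls made up 45.5%, but 50.4% with median-of-ratios scaling, 51.8% with quantile normalisation and 50.4% without genes that follow the fibroblast markers. Over this contrast and the 8 pairwise comparisons there were 108 list calls, of which 2 held with an estimated correlation.

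Epigenetic regulators, which the series names as targets, changed as single genes, while most of their lists did not pass. Dnmt1, the maintenance methyltransferase (chromosome 9, 20907209 to 20959888), had 80.5 ± 3.23 TPM in SL, 147 ± 6.34 in 2iL, 104 ± 2.65 in A2iL, 135 ± 0.513 in LCDM and 119 ± 1.27 in 2iL-F. Dnmt3b (chromosome 2, 153649450 to 153687730) had 216, 8.28, 96.9, 53.6 and 21.7 TPM in the same order. The methylation writers as a list passed in no comparison, with a lowest adjusted p of 0.185 in A2iL against SL. Endogenous retroviruses themselves were not analysed here. Of the 32 genes tested that silence retroelements, Trim28, the KAP1 corepressor (chromosome 7, 12999114 to 13031035), changed by -0.50 ± 0.04 in 2iL and -0.27 ± 0.04 in A2iL against SL, and did not pass in LCDM (0.01, adjusted p = 0.822) or 2iL-F (-0.10, adjusted p = 0.0614, and 0.0399, 0.0401 and 0.043 without 2iL replicate 3, 2iL replicate 5 and 2iL-F replicate 3). Setdb1, the H3K9 methyltransferase recruited by it (chromosome 3, 95323525 to 95357202), had 30.5 ± 0.658 TPM in SL and 24.3 ± 1.46 in 2iL (-0.32 ± 0.05). It also fell in 2iL-F (-0.28 ± 0.05) and did not pass in A2iL (0.02, adjusted p = 0.73) or LCDM (-0.04, adjusted p = 0.529). As a list these genes passed in no comparison, with a lowest adjusted p of 0.186 in LCDM against A2iL, and neither did H3K9 methylation (0.251) or Polycomb genes (0.151).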

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

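Tests with the named part of the table alone, without the libraries labelled 2iL and 2iL-F, without genes that follow the fibroblast markers and with restored symbols were chosen after the results were seen. Counts of changed genes stayed within 1.5 times under every setting but the first of these, including 100 of 100 counts without one library, where the lone library of a group is assumed to vary like the others. In the named part alone, where fewer genes are tested, the counts were 6469 (2iL vs SL), 4835 (A2iL vs SL), 5664 (LCDM vs SL), 5645 (2iL-F vs SL), 5332 (2iL-F vs 2iL), 5872 (A2iL vs 2iL), 5335 (LCDM vs 2iL), 4826 (LCDM vs A2iL), 6080 (mean) and 7543 (F test), against 11321, 7844, 9607, 9540, 8995, 10127, 9075, 7873, 10421 and 13139 over all genes. Without the libraries labelled 2iL and 2iL-F they were 8273 (A2iL vs SL), 9972 (LCDM vs SL), 8317 (LCDM vs A2iL), 9522 (mean) and 11400 (F test). Without the 1126 genes that follow the fibroblast markers they were 10188, 7267, 8622, 8851, 7847, 8992, 8055, 7015, 9374 and 12044, in the first order. With the replicate block they were 11241, 7618, 9484, 9413, 8858, 9995, 8869, 7604, 10314 and 13015; 378 of 378 list tests stayed on the same side of the threshold, and 5 of 1636 named-gene results lost their call. Library differences of the same number correlated at -0.13 to 0.07 between conditions, and 4 of 10 libraries correlated best with their own number. No broad effect of the number was thus seen. A small effect, or an effect on few genes, would not show in correlations over all tested genes.

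Lists that passed, in the order 2iL, A2iL, LCDM and 2iL-F vs SL, 2iL-F, A2iL and LCDM vs 2iL, LCDM vs A2iL and mean, numbered 13, 8, 19, 14, 6, 10, 6, 15 and 17. With an estimated correlation they were 0, 0, 0, 0, 1, 0, 0, 1 and 0, where by construction camera also tests on the 5 residual degrees of freedom; the interferon list's estimated correlation was 0.001. With fry, which tests members against no change, they were 38, 31, 38, 32, 37, 39, 29, 36 and 38. With restored symbols they were 17, 15, 26, 15, 7, 16, 9, 21 and 20. The fry direction was opposite to that of camera for LIF-STAT3 targets in 2iL vs SL (adjusted p = 0.013), A2iL vs 2iL (2.92e-05) and LCDM vs 2iL (0.0115), blood and macrophage markers in 2iL-F vs SL (0.0056), endothelial markers in A2iL vs 2iL (0.00305), mesoderm in LCDM vs 2iL (0.035) and BMP-SMAD targets in LCDM vs A2iL (0.0063). With quantile normalisation the log2 change turned for Tmem132c in A2iL vs 2iL (-0.03), Tet3 in 2iL vs SL (0.23) and Spry4 in 2iL-F vs 2iL (-0.39). Without the libraries labelled 2iL and 2iL-F it turned for Cdh1 (-0.02) and Bmp4 (0.54) in the mean contrast, which then holds fewer conditions. Except where stated, the cause was not tested. Of 1636 named-gene results, 1624 kept their direction and side of the threshold with median-of-ratios scaling (factors 0.971 to 1.05), 1628 with a pseudocount of 0.1 and 1613 with quantile normalisation. Depth is unknown, so what it limits cannot be given.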

Other observations

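The tests that weigh the feeder labels, the line offset and the germline genes below were chosen only after the results were seen; the list tests were planned. The following list results were not described above. Glycolysis genes were higher in A2iL than in SL, where 10 of 17 tested members rose and 2 fell, with 10 that rose and 3 that fell adjusted over the list alone (adjusted p = 0.00991, and adjusted p = 0.54 with an estimated correlation); Ldhb, a lactate dehydrogenase subunit, had 418 ± 3.81 against 91.4 ± 3.96 TPM, and Aldoc, an aldolase, rose by 2.26 ± 0.09. Fatty acid synthesis genes were lower in LCDM than in 2iL, where 10 of 16 tested members fell and 2 rose (adjusted p = 0.00633, and adjusted p = 0.674 with an estimated correlation), with malic enzyme, Me1, at -1.27 ± 0.11. H3K4 methylation genes were higher in 2iL-F than in SL, where 6 of 11 tested members rose and 1 fell, with 7 that rose and 1 that fell adjusted over the list alone (adjusted p = 0.0455, and adjusted p = 0.5 with an estimated correlation, and adjusted p = 0.0798 with members by restored symbols), with Wdr5, a core subunit of the methyltransferase complexes, at 1.21 ± 0.06. LIF-STAT3 targets had 11 of 16 tested members that rose and 4 that fell in the same pair (adjusted p = 0.0455, and adjusted p = 0.544 with an estimated correlation, and adjusted p = 0.0693 with median-of-ratios scaling), with Mras, a Ras family member, at 1.65 ± 0.07. Both directions rest on libraries labelled 2iL-F, whose feeder state is in doubt.

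In LCDM, imprinted genes were lower than in SL, where 13 of 21 tested members fell and 5 rose (adjusted p = 0.0361, and adjusted p = 0.56 with an estimated correlation): Ndn, a paternally expressed growth suppressor, had 5.44 ± 0.0884 against 28.3 ± 0.532 TPM. Primitive endoderm genes were also lower, where 12 of 20 tested members fell and 5 rose (adjusted p = 0.0396, and adjusted p = 0.479 with an estimated correlation, adjusted p = 0.0589 with median-of-ratios scaling and 0.0529 with a pseudocount of 0.1), with Lrp2, an endocytic receptor, at -3.02 ± 0.10 and the basement membrane collagen Col4a1 at -1.95 ± 0.07. Against A2iL, hypoxia genes had 11 of 17 tested members that fell and 3 that rose (adjusted p = 0.00227, and adjusted p = 0.486 with an estimated correlation), with the peptide hormone Adm at -2.58 ± 0.09. Excision and mismatch repair genes had 20 of 37 tested members that rose and 1 that fell (adjusted p = 0.0369, and adjusted p = 0.711 with an estimated correlation, and adjusted p = 0.0501 with median-of-ratios scaling), with Pold2, a DNA polymerase subunit, at 0.90 ± 0.09. The fibroblast marker sum was 1698 ± 31.8 TPM in LCDM, 7941 ± 223 in SL and 4880 ± 31.8 in A2iL. Of the 42 lists, 13 passed in no comparison. Their lowest adjusted p was 0.0574 for neural, 0.0848 for heat shock, 0.0969 for unfolded protein response, 0.138 for BMP-SMAD, 0.155 for blood and macrophage, 0.17 for mesoderm, 0.185 for telomere maintenance, 0.189 for Src family kinase and 0.399 for endothelial genes. By restored symbols, camera passed neural (0.0285) in 2iL vs SL, and BMP-SMAD in A2iL vs SL (0.00773), LCDM vs SL (0.0499) and the mean contrast (0.0374). It also passed mesoderm in LCDM vs SL (0.0288), and blood and macrophage in A2iL vs 2iL (0.0338) and LCDM vs A2iL (0.00878). Neural genes passed in 2iL vs SL with median-of-ratios scaling too (0.0464). DNA methylation writers, retroelement silencing, H3K9 methylation and Polycomb genes are given above. Of the 4 lists too small to test, the two-cell-like list had Tmem132c and Arg2, at 0.603 and 0.707 TPM in 2iL and 1.91 and 0.681 in 2iL-F. Of its 37 symbols in the deposited table only 3 lie in the named part, so these values do not describe the list. The receptor list had Parp1, and the mitochondrially encoded and sex-linked lists had 0 tested members. The 6 sex-linked symbols all lie outside the named part.

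Fibroblast markers were lower in the libraries labelled 2iL than in those labelled 2iL-F, with a median log2 difference of 4.54. An exchange of these labels stays open, since that difference is the pattern itself and cannot test it. Removal of feeders before RNA was taken from the libraries labelled 2iL, with every label right, is argued against as the whole cause. The libraries labelled 2iL-F would then hold far less of the markers than A2iL, unless their stem cells express these genes. Their median log2 difference from A2iL was 0.03 (95% interval over the 43 markers -0.38 to 0.47). The interval takes the markers as independent and measures the spread among them, not that between cultures. Expression of these genes by the stem cells labelled 2iL-F cannot be told apart from fibroblasts: the order of the markers followed that of A2iL with a Spearman rho of 0.84, which either source could give, and SL followed A2iL with 0.57. No library was moved to another group.

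In the lower part of the table, symbols of broadly expressed genes stand beside values near 0. That these genes are low in the cells is argued against by 93.5% of broadly expressed members having at least 5 TPM on the next line, against 45.8% on their own. An offset of 1 line in that stretch fits, with an area under the curve of 0.982 for the next line. How the offset arose, and whether lines are missing, was not tested.

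Germline genes were higher in LCDM than in A2iL, with a median log2 difference of 1.16, and of 0.82 over 37 members by restored symbols. Less fibroblast RNA in LCDM would raise all stem cell genes alike. The core pluripotency median was lower than the germline median, at 0.27, and at 0.31 by restored symbols. Of the named members, 13 of 17 lay above 0.27 by more than the largest SE of 0.2. By restored symbols 21 of 37 lay as far above 0.31. These counts cannot decide whether less fibroblast RNA is the whole cause. The germline median of 1.16 alone puts most named members above that mark, and the cut-off was set after the values were seen. Lower de novo methyltransferase transcripts could apply only to Dnmt3b and the cofactor Dnmt3l. Dnmt3a was higher in LCDM than in A2iL, as the changes of both against 2iL given above show. For Dnmt3b and Dnmt3l this cause cannot be told apart from others. Germline genes were higher in LCDM than in 2iL-F, where Dnmt3b was lower (21.7 against 53.6 TPM), by a median of 0.77 (95% interval 0.02 to 1.8) over named members but 0.08 (-0.98 to 0.77) by restored symbols. Both intervals take the members as independent and measure the spread among them, not that between cultures. Against SL, the named members did not pass in 2iL (9 rose and 6 fell, adjusted p = 0.252, and adjusted p = 0.656 with an estimated correlation) or 2iL-F (7 rose and 7 fell, adjusted p = 0.771, and adjusted p = 0.898 with an estimated correlation), while by restored symbols, with the preset correlation alone, they passed as higher in both (adjusted p = 0.00747 and adjusted p = 0.0039).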
